A study of Mus musculus with 31 samples.

How the data were processed

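Total RNA of whole retina from C57BL/6J mice was measured on 31 single-colour Illumina BeadChip arrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned and treated with DNase on RNeasy columns, checked on a Bioanalyser, and turned into biotinylated cRNA with the Ambion TotalPrep kit. The submitters' processing notes name BeadStudio, and its version and settings are not given in the sources used here. Groups and replicate numbers were taken from the labels: 8 wild-type, 9 Ins2Akita, 8 untreated and 6 STZ samples, with hyperglycaemia of 3 months in the series' design text. The STZ and untreated groups served as one comparison and the Ins2Akita and wild-type groups as the other. Nothing says whether the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

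The authors deposited probe intensities on a linear scale in a pair of tables. The table called not normalized held intensity values that, from the values themselves, had been background-subtracted and scaled by the authors to one mean of 351.836 on every array, with a lowest value of -22.7772. The deposited series matrix held intensities with a mean of 403.64 on every array and background not subtracted. On each array it was a linear function of the other table to within 0.0106596, and its medians per array were 74.0152 to 95.7908. Its scale is therefore linear, its values are not centred per gene, and a direction does not arise with 1 colour. The deposited table also gave a detection p-value per probe and array, computed by the authors with BeadStudio per the labels. Because scaling and subtraction preceded deposit, differences in total RNA signal between arrays cannot be seen, and dim probes carry more error.

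Probes were named from the platform annotation, updated through Entrez identifiers to a list of genes of assembly GRCm38.p6, used for names only, and probe sequences were not used here. Of 25697 probes, 23978 had 1 symbol, 0 had several and 1719 were unlisted, and 23962 matched that list. A further background step and quantile normalization were run with neqc of limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with an offset of 16, giving log2 values. Fold changes of dim probes are understated on this scale because of the offset. Probes were kept if the deposited detection p was under 0.05 on at least 6 arrays, the size of the smallest group. This left 16743 probes, of which 15730 had a symbol, for 11172 genes, and 6966 probes were detected on 0 arrays. The depth of an array was taken as its number of detected probes, 14581 to 16460.

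A linear model with 4 group means over all 31 arrays was fitted per probe with lmFit and eBayes of limma. Its contrasts were Ins2Akita minus wild type, STZ minus untreated, the difference of these changes, their mean, and untreated minus wild type. P-values were two-sided and adjusted by Benjamini-Hochberg over the probes kept, with calls at an adjusted p under 0.05. Of 42 gene lists fixed before the data were examined, together with the design, the groups and the rule for named genes, 41 had at least 4 measured genes. They were tested with camera at a preset correlation of 0.01, with the brightest probe of each gene, and with an estimated correlation and fry as alternatives. Because the labels assign groups the same replicate numbers, a fit with the number as a block was also run. The scores of the interferon, Muller glia, microglia and complement lists alone were compared by exact permutation of the arrays of a pair of groups. This comparison was not part of the fixed design. Its adjustment covers these 8 tests and not all 41 lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

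Genes were named by rule: for each diabetes comparison the 8 largest rises and 8 largest falls among the calls, up to 4 members with the smallest p of each list called or holding 2 or more called members, up to 10 genes called in both models, and Ins2, Txnip, Gfap and Vegfa. For the difference between the models and for untreated against wild type, the 5 genes with the smallest p were named. Where fewer passed, the rest were named as not passing. Unnamed clones and gene models were skipped among the largest changes, and genes with near-identical copies were named as uncertain.

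On simulated data with the arrays' own spread, 67, 67 and 66 of 16743 probes were changed by 0.25, 0.5 and 1 on the log2 scale. For Ins2Akita against wild type 22.4%, 71.6% and 98.5% of them were called, and 4.5% of the calls were false. For STZ against untreated 16.4%, 73.1% and 98.5% were called, with 6.7% false. With no change simulated, 0 probes were called in either comparison. A shift of 0.25 in the 15 interferon genes gave an adjusted p of 2.56e-07 and 1.1e-06 by camera, and 0 other lists of 41 were called. The simulated noise was independent between probes, so this cannot show how often lists of correlated genes are called falsely. Random splits of the real arrays gave a median of 4 lists for Ins2Akita and wild type (up to 19). For STZ and untreated the median was 5 (up to 15).

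The alternatives were no background step, median scaling, the series matrix values on the log2 scale with a floor of 16, no filter or detection at a p under 0.01 on every array, a trended robust prior, array weights, only the groups compared, the replicate number or the BeadChip as a block, Ins2Akita replicate 9 left out, the mean of a gene's probes, and each array left out in turn. Further alternatives were chosen after seeing the data: scores of 4 lists of neighbouring tissues (lens fibre other than crystallins, pigment epithelium and melanocyte, skeletal muscle, liver and plasma) as covariates, anterior eye scores (the ciliary, iris and cornea list and a conjunctival list) as covariates, and 4 arrays that stood apart in lens or muscle markers left out. The liver and plasma list and a list of conjunctival epithelium were likewise added after seeing the data, as were the comparison of list scores without each array and that of signs with separate sets of 4 wild-type arrays. All samples were used.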

Results

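Gene expression in the mouse retina was measured in a pair of models of insulin-deficient diabetes. One was the Ins2Akita mouse, which carries a dominant mutation of the insulin gene Ins2 that leads to the loss of pancreatic beta cells. The other was the mouse made diabetic with streptozotocin (STZ), a compound toxic to beta cells. All mice were on the C57BL/6J background, and the diabetic groups had been hyperglycaemic for 3 months. RNA from whole retina was hybridised to 31 single-colour Illumina BeadChip arrays, of which 8 were from wild-type mice, 9 from Ins2Akita mice, 8 from untreated mice and 6 from STZ mice. Of 25697 probes, 14581 to 15469 per array were detected in the wild-type group, 15395 to 16460 in the Ins2Akita group, 15226 to 15650 in the untreated group and 15074 to 15816 in the STZ group. Array data have no read depth. The precision of a value depends on the number of arrays and, for dim probes, on signal over background. Pairs of arrays correlated at 0.954 to 0.994 over the 16743 probes kept, with a median of 0.982 within groups and 0.979 between groups. No arrays held duplicate values. By the array positions in the labels, each group lay on a BeadChip of its own, except that Ins2Akita replicate 9 shared the BeadChip of the STZ group.

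The insulin gene Ins2 itself, mutated in the Ins2Akita line, had 1 probe, which was detected on 2 of the 31 arrays and was left out of the tests. Its retinal level therefore checks no label.

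The first comparison asked how the retina of Ins2Akita mice differed from that of wild-type mice. Ch25h, which encodes an enzyme that makes an oxysterol from cholesterol, rose 2.01-fold (log2 change 1.01, SE 0.279, adjusted p = 0.0347, n = 9 and 8). The secreted metalloprotease gene Adamts19 rose 1.62-fold (log2 change 0.70, SE 0.171, adjusted p = 0.0164). Egr1, an immediate early transcription factor, fell by 1.78 on the log2 scale to 0.291 of its wild-type level (SE 0.451, adjusted p = 0.0202). S100a8 and S100a9, whose products form the calcium-binding protein calprotectin of neutrophils, fell by 1.02 and by 0.76 on the log2 scale (SE 0.245 and 0.209, adjusted p = 0.015 and 0.034), and were detected on 3 and 1 of 9 Ins2Akita arrays against 8 and 6 of 8 wild-type arrays. Vegfa, the main growth factor of blood vessels, rose 1.2-fold on its brightest probe (log2 change 0.26, SE 0.0646, adjusted p = 0.0193). Its other probe gave 0.06 (adjusted p = 0.759).

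**Figure D1:**
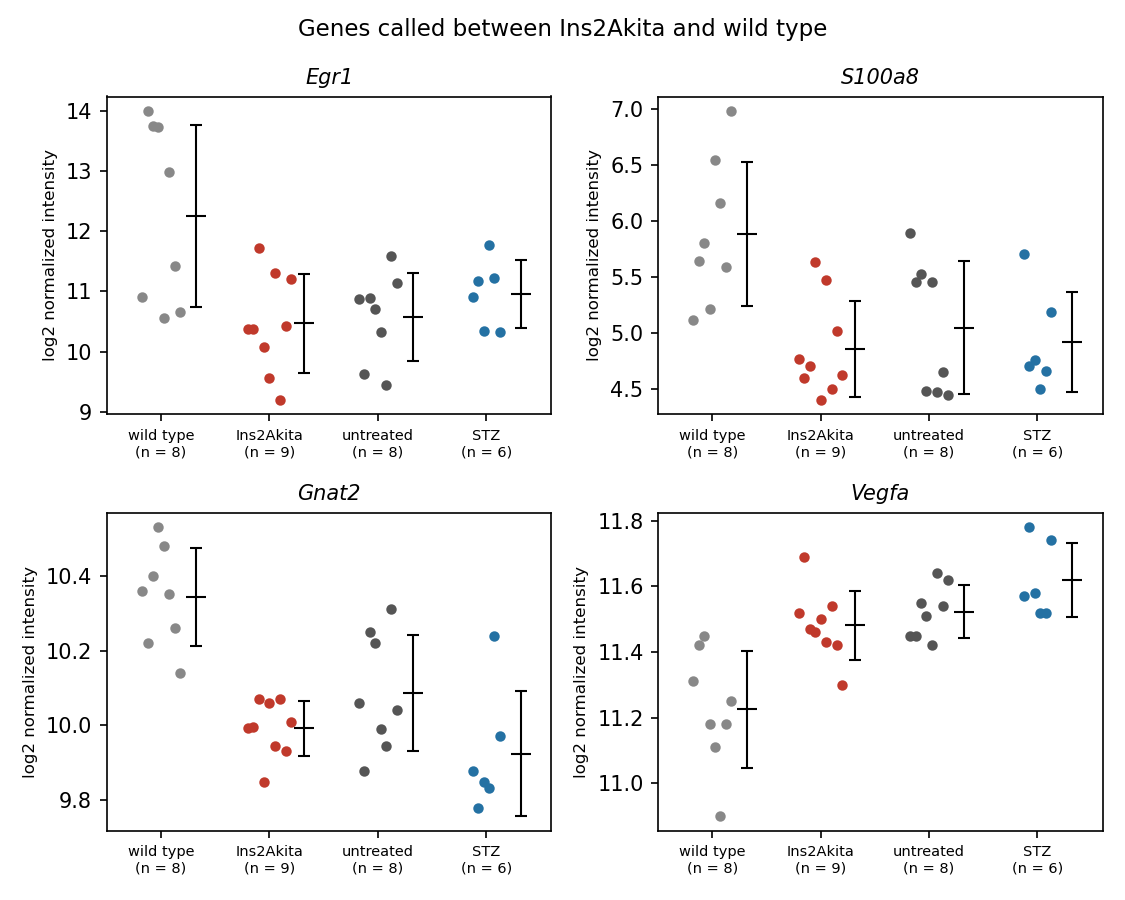
Normalized log2 intensity of Egr1, S100a8, Gnat2 and Vegfa on each array (points) in the wild-type (n = 8), Ins2Akita (n = 9), untreated (n = 8) and STZ (n = 6) groups, with the group mean (bar) and SD (whisker). Egr1 spanned 10.56 to 14 in wild type against 9.2 to 11.72 in Ins2Akita, and the untreated arrays lay at 9.44 to 11.59.

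Across the array 696 of 16743 probes (4.16%) passed an adjusted p of 0.05 in limma, 295 higher and 401 lower in Ins2Akita, and 488 genes passed on their brightest probe. Changes were small, with a median of 1.24-fold, and 17 probes changed by more than 1.5-fold. Further large rises were those of Bcl9, a coactivator of Wnt signalling (log2 change 0.67, SE 0.128, adjusted p = 0.00394), the ribosomal protein gene Rpl23 (0.66, SE 0.0632, adjusted p = 1.68e-07) and Selenbp1 (0.62, SE 0.15, adjusted p = 0.0163). They also included Smagp (0.59, SE 0.16, adjusted p = 0.0319), Nat8 (0.55, SE 0.136, adjusted p = 0.0184) and the collagen gene Col27a1 (0.51, SE 0.126, adjusted p = 0.0172). Mrgpra2b fell by 0.62, Zpld2 by 0.57, the potassium channel subunit gene Kcne2 by 0.56 and the claudin gene Cldn7 by 0.55 on the log2 scale (adjusted p = 0.00174, 0.000752, 0.000752 and 0.012). Jrk was detected on 6 of 8 wild-type arrays and on 0 of 9 Ins2Akita arrays, and was at least 1.23-fold lower in Ins2Akita (adjusted p = 0.00174), a bound set by the lowest detected signal of each Ins2Akita array. Detection was also uneven for Ch25h (3 of 8 wild-type and 8 of 9 Ins2Akita arrays), Adamts19 (3 of 8 and 9 of 9) and Nat8 (1 of 8 and 7 of 9). The other 3 probes of Rpl23 gave log2 changes of -0.14, -0.27 and -0.05 and were not called, and the other probe of Smagp gave 0.01, so that these calls rest on single probes. Probe sequences were not used here, so cross-hybridisation and sequence variants under the probes were not checked. Rpl23 and Mrgpra2b belong to families with near-identical copies, and their probe values are uncertain for that reason.

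Several of these genes also differed in the same direction between the untreated and the wild-type mice, both non-diabetic. This comparison shares its wild-type arrays with the first, which alone makes signs coincide. Of the 696 probes 586 (84.2%) had the same sign, against a median of 91.3% of as many probes in 100 simulations with no change in either group. With Ins2Akita and untreated set against separate sets of 4 wild-type arrays, a median of 68.6% of the 696 probes with the smallest p did (53.6 to 79.3 over 70 splits). Egr1 was lower in the untreated group by a log2 difference of -1.68 (adjusted p = 0.00921) and S100a8 by -0.83 (adjusted p = 0.0166). Rpl23 was higher in the untreated group by 0.65 (adjusted p = 1.53e-08), Col27a1 by 0.89 (adjusted p = 1.05e-05), Bcl9 by 0.51 (adjusted p = 0.00573) and the brightest probe of Vegfa by 0.30 (adjusted p = 0.00157), while the other Vegfa probe gave -0.07. Mrgpra2b, Zpld2, Kcne2, Jrk and the cone gene Gnat2 were lower in the untreated group, by log2 differences of -0.49, -0.49, -0.43, -0.40 and -0.25 (adjusted p = 0.00151, 0.000254, 0.001, 0.0067 and 0.00857), Jrk being detected on 1 of 8 untreated arrays. No such difference was detected for Ch25h (0.27, adjusted p = 0.537) or Adamts19 (0.31, adjusted p = 0.208).

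Of 13 cone genes 11 lay below 0 in Ins2Akita, and of 19 rod genes 12. The cone list was lower by camera, a test of whether a list moves more than other genes (adjusted p = 0.0194), and this call was lost (adjusted p = 0.607 with an estimated correlation). It was also lost without wild-type replicate 5 or Ins2Akita replicate 4 (adjusted p = 0.0842 and 0.0722), or with anterior eye scores as covariates (0.0514). In it 0 genes rose, 1 fell and 12 did not pass, with 2 lower when adjusted over the list alone. The member that fell was Gnat2, the cone transducin alpha subunit (log2 change -0.35, SE 0.0678, adjusted p = 0.00402). Pde6h, a cone phosphodiesterase subunit, gave -0.22 (adjusted p = 0.0944). Against the same wild-type arrays 9 of the 13 cone genes also lay below 0 in the untreated group. The median log2 change of the cone list was -0.153 there and -0.162 in Ins2Akita. Camera did not call it in the untreated group (adjusted p = 0.353). Of the 19 rod genes 1 rose in Ins2Akita, 3 fell and 15 did not pass, or 2 and 8 adjusted over the list alone. Camera did not call the rod list in Ins2Akita (adjusted p = 0.143). The rod exchanger gene Slc24a1 fell by 0.32, the phosphodiesterase gene Pde6b by 0.29 and the retinoid transporter gene Abca4 by 0.27 on the log2 scale (adjusted p = 0.00443, 0.0196 and 0.0426), while Prph2, which shapes the disc rim, rose by 0.32 (adjusted p = 0.00612). The other 2 probes of Abca4 gave -0.20 and -0.27 and were not called.

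Genes of the ribosome and of mitochondrial respiration formed the largest lists that differed. The cytosolic ribosome list was lower by camera (57 genes, adjusted p = 5.38e-07, median log2 change -0.12), with adjusted p = 0.607 with an estimated correlation. In it 1 gene rose, 9 fell and 47 did not pass, or 1 and 17 adjusted over the list alone, and Rps21 (-0.29), Rpl19 (-0.40) and Rpl36a (-0.41) were among those that fell (adjusted p = 0.00329, 0.00595 and 0.00805). Ribosomal protein genes have many processed copies, so single members are uncertain. The oxidative phosphorylation list was also lower by camera (74 genes, adjusted p = 0.0127, median -0.08), with adjusted p = 0.709 with an estimated correlation, and it turned to higher without passing in the authors' series matrix values (adjusted p = 0.788). Without wild-type replicate 6 it was not called (adjusted p = 0.192). In it 2 genes rose, 7 fell and 65 did not pass, or 3 and 12 adjusted over the list alone. The respiratory chain genes Ndufb5 (-0.43), Cox7c (-0.35) and Ndufa6 (-0.35) fell (adjusted p = 0.00447, 0.00612 and 0.00652), and the ATP synthase gene Atp5g3 rose (0.23, adjusted p = 0.0053). Against the same wild-type arrays both lists were also lower by camera in the untreated group. Their medians there were -0.14 for the ribosome (adjusted p = 9.73e-06) and -0.12 for oxidative phosphorylation (adjusted p = 1.55e-05). Of 34 proteasome genes 0 rose and 2 fell, or 1 and 2 adjusted over the list alone, the regulatory subunit genes Psmd8 (-0.29, adjusted p = 0.0125) and Psmd11 (-0.35, adjusted p = 0.0132), and camera did not call the list (adjusted p = 0.2).

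The amacrine and horizontal cell list was higher by camera in Ins2Akita (15 genes, adjusted p = 0.0127), with adjusted p = 0.607 with an estimated correlation and 0.0503 with the mean of all probes of a gene. Over all genes 0 of the 15 passed in limma and 4 had an unadjusted p under 0.05, 4 were higher when adjusted over the list alone, and 14 lay above 0. The smallest p-values were those of the cholinergic genes Chat (log2 change 0.30, SE 0.0952, adjusted p = 0.0704) and Slc5a7 (0.29, SE 0.102, adjusted p = 0.096). The other probe of Chat gave 0.04 (adjusted p = 0.824), and the brightest passed with the anterior eye scores as covariates (0.36, adjusted p = 0.0265). The member Tfap2b, at 0.23 on its brightest probe (adjusted p = 0.106), fell on another (-0.25, adjusted p = 0.00997). The amacrine list had a mean log2 change of 0.127 in Ins2Akita. Against the same wild-type arrays its mean was 0.145 in the untreated group, where 3 of its genes were called higher. Camera did not call the list there (adjusted p = 0.326). In the angiogenic and neurotrophic list 2 of 10 genes rose, over all genes and adjusted over the list alone, Vegfa on its brightest probe and the lymphatic growth factor gene Vegfc (1.31-fold, log2 change 0.39, SE 0.0956, adjusted p = 0.0163), and camera did not call the list (adjusted p = 0.0984). Of 10 bipolar cell genes 1 rose and 1 fell, or 1 and 2 adjusted over the list alone, the protein kinase gene Prkca (0.31, adjusted p = 0.0187) and Pcp2 (-0.27, adjusted p = 0.0469), both markers of rod bipolar cells (camera adjusted p = 0.527). Of 15 ganglion cell genes Gap43 rose (0.34, adjusted p = 0.00652) and Uchl1 fell (-0.23, adjusted p = 0.0499), with 1 and 1 also adjusted over the list alone (camera adjusted p = 0.587). Of 11 pericyte and smooth muscle genes 0 rose and 2 fell, over all genes and adjusted over the list alone, Vtn (-0.30, adjusted p = 0.0147) and Cspg4 (-0.42, adjusted p = 0.0209). Vtn is also a member of the liver and plasma list, at log2 intensities of 12.13 to 12.87 over all arrays. Its fall therefore does not single out pericytes. The median of the pericyte and smooth muscle list was -0.02 and its mean 0.06, and camera did not call it (adjusted p = 0.408).

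In the list of polyol, hexosamine and glucose-sensing genes 0 of 9 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.582, median 0.06, mean -0.02). The 2 were the pentose phosphate pathway genes Tkt (-0.34, adjusted p = 0.00805) and Taldo1 (-0.29, adjusted p = 0.0147), and the other 2 probes of Tkt gave -0.14 and -0.20 and were not called. Txnip, a gene induced by glucose, did not pass (log2 change 0.17, SE 0.152, adjusted p = 0.583). Of 21 antioxidant genes the metallothionein gene Mt3 rose (0.34, adjusted p = 0.0444) and Gpx4 fell (-0.27, adjusted p = 0.0297), whose other probe gave 0.17, with 1 and 1 also adjusted over the list alone (camera adjusted p = 0.582). Gfap, the marker of gliosis, did not pass (log2 change 0.12, SE 0.0977, adjusted p = 0.529) and was detected on 2 of 8 wild-type and 5 of 9 Ins2Akita arrays. Chrnb1, a subunit of the muscle-type acetylcholine receptor, rose 1.34-fold on one probe (log2 change 0.42, SE 0.104, adjusted p = 0.0164), and its other probe gave 0.35 and did not pass (adjusted p = 0.105).

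Markers of tissues next to the retina varied between arrays. The retinal pigment epithelium and melanocyte list was higher in Ins2Akita by camera (15 genes, adjusted p = 0.0127, median log2 change 0.78), with adjusted p = 0.709 with an estimated correlation. It was not called with the scores of 4 neighbouring-tissue lists, itself among them, as covariates (adjusted p = 0.918), with those of 2 anterior eye lists (0.228), or without wild-type replicates 6 or 8 or Ins2Akita replicates 1 or 4 (0.0722 to 0.0864). Of its genes 0 passed over all genes in limma or adjusted over the list alone, while 2 had an unadjusted p under 0.05. Ttr, abundant in pigment epithelium, gave 1.01 (SE 0.454, adjusted p = 0.211) and Rrh 0.20 (SE 0.0888, adjusted p = 0.212). The list's score per array, the mean log2 level of its genes relative to all arrays, was 0.37 ± 0.899 in Ins2Akita (SD, n = 9) and -0.289 ± 1.00 in wild type (SD, n = 8). The crystallin score was -0.821 ± 2.45 in Ins2Akita and 0.55 ± 2.2 in wild type. Single arrays stood apart for Ch25h, Rpl19, Pde6b, Abca4, Tkt, Uchl1 and Cspg4.

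The split of the calls, 295 higher and 401 lower, moved with the scaling. It was 146 and 374 with median scaling and 470 and 3483 in the authors' series matrix values. In those values, whose background was not subtracted, the median log2 change of all probes was -0.086, against -0.000922 in the fit as planned. The cone and ribosome lists were not called by camera there (adjusted p = 0.309 and 0.368). The count was 448 with only these groups in the fit, 446 with the scores of 4 neighbouring-tissue lists as covariates, and 228 with the BeadChip as a random block. That block left the changes of the 696 probes at a median of 0.996 of their size and multiplied their SE by a median of 1.12. With the wider SE Egr1 (-1.76, SE 0.503, adjusted p = 0.0662), Vegfa (0.25, SE 0.0719, adjusted p = 0.0662), S100a8 (-1.03, SE 0.274, adjusted p = 0.0505), Ch25h (1.01, SE 0.312, adjusted p = 0.0939) and Chrnb1 (0.42, SE 0.116, adjusted p = 0.0574) no longer passed. Groups and BeadChips nearly coincide, so these losses do not bear on an effect of the BeadChip. With the anterior eye scores Ch25h gave 0.76 (SE 0.223, adjusted p = 0.0555).

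**Figure D2:**
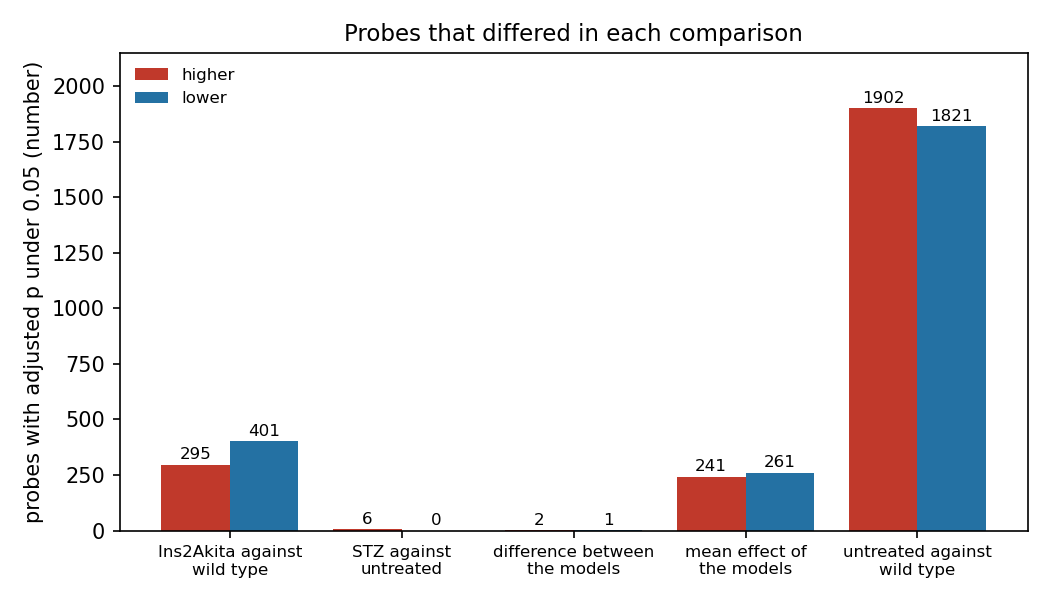
Number of probes with an adjusted p under 0.05 in each comparison (vertical axis), split into higher (red) and lower (blue). The comparison of the non-diabetic groups, untreated against wild type, gave 3723 probes, against 696 for Ins2Akita and 6 for STZ.

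The second comparison asked the same of STZ mice against untreated mice. Few genes passed, and Gbp3, Oasl2, Rsad2 and Trim30a among them are known to be induced by interferon. Chrnb1 rose 1.66-fold (log2 change 0.73, SE 0.115, adjusted p = 0.00749, n = 6 and 8), and its second probe rose by 0.74 (adjusted p = 0.0303). Between untreated and wild type the first of these probes gave -0.035 (adjusted p = 0.85), while the second was lower in the untreated group (-0.43, adjusted p = 0.0162). The guanylate-binding protein gene Gbp3 rose 1.54-fold (log2 change 0.63, SE 0.109, adjusted p = 0.0141), the antiviral genes Oasl2 1.72-fold (0.78, SE 0.135, adjusted p = 0.0141) and Rsad2 1.66-fold (0.73, SE 0.138, adjusted p = 0.0303), and Trim30a 1.82-fold (0.87, SE 0.171, adjusted p = 0.048). Trim30a was detected on 2 of 8 untreated and 6 of 6 STZ arrays. With the scores of 2 anterior eye lists as covariates none of these 4 interferon-inducible genes passed. Gbp3 then gave 0.52 (SE 0.109, adjusted p = 0.06), Oasl2 0.63 (SE 0.147, adjusted p = 0.099), Rsad2 0.71 (SE 0.148, adjusted p = 0.06) and Trim30a 0.66 (SE 0.175, adjusted p = 0.145).

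**Figure D3:**
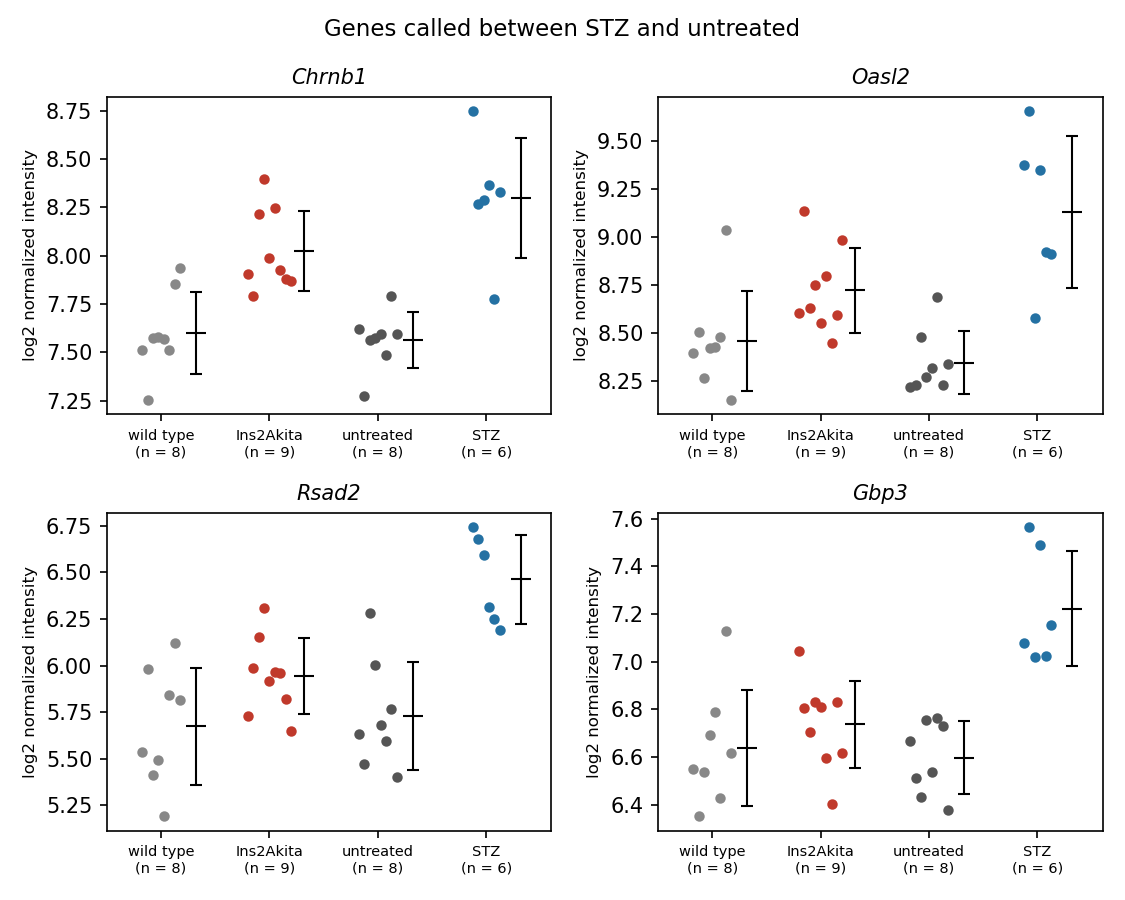
Normalized log2 intensity of Chrnb1, Oasl2, Rsad2 and Gbp3 on each array (points) in the wild-type (n = 8), Ins2Akita (n = 9), untreated (n = 8) and STZ (n = 6) groups, with the group mean (bar) and SD (whisker). The STZ arrays lay at 7.02 to 7.56 for Gbp3 against 6.38 to 6.76 in the untreated group.

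These 6 probes of 5 genes, all higher, were the calls of limma among 16743 probes, and 1431 probes had an unadjusted p under 0.05. The second probe of Gbp3 gave 0.70 (adjusted p = 0.0671) and that of Oasl2 0.31 (adjusted p = 0.564). Gbp3, Trim30a and Oasl2 belong to families of similar genes, and their probe values are uncertain for that reason.

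The interferon response list was higher in STZ by camera (15 genes, adjusted p = 2.11e-14), and the call held with an estimated correlation (adjusted p = 0.0297). All 15 genes lay above 0, with a mean log2 change of 0.47. Ciliary, iris and cornea markers were higher in the same comparison, with 10 of 10 genes above 0 and a mean of 0.615. With the anterior eye scores as covariates 13 of the 15 interferon genes lay above 0 with a mean of 0.347, and the list was called (adjusted p = 1.98e-08, and adjusted p = 0.0444 with an estimated correlation). In the fit without those scores 2 of the 15 genes rose (Gbp3 and Rsad2), 0 fell and 13 did not pass, and 9 rose when adjusted over the list alone. Usp18 gave 1.00 (2-fold, SE 0.247, adjusted p = 0.137) and Gbp2 0.59 (1.5-fold, SE 0.138, adjusted p = 0.11). The list's score was above the untreated mean on 6 of 6 STZ arrays and above the highest untreated array on 5 (difference 0.472, exact permutation p = 0.000666, two-sided, adjusted p = 0.00533 over 8 such tests). In Ins2Akita the same score differed by 0.149 (exact permutation p = 0.153, adjusted p = 0.217) and camera did not call the list (adjusted p = 0.143). Both depended on wild-type replicate 7, whose score stood apart. Without it the score was above the wild-type mean on 9 of 9 Ins2Akita arrays (difference 0.237, exact permutation p = 0.00245, unadjusted), and camera called the list higher (adjusted p = 0.00727, and adjusted p = 0.359 with an estimated correlation). The difference between the models was called by camera on all arrays (adjusted p = 0.000138, and adjusted p = 0.519 with an estimated correlation) and without that array (adjusted p = 0.00416, and adjusted p = 0.683 with an estimated correlation).

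The Muller glia list was higher in STZ (15 genes, adjusted p = 0.000449), and this call also held with an estimated correlation (adjusted p = 0.0297). In it 0 genes passed over all genes in limma and 5 had an unadjusted p under 0.05, 1 was higher when adjusted over the list alone, and 13 of 15 lay above 0. Hes1, a target of Notch signalling, gave 0.43 (SE 0.122, adjusted p = 0.216), Clu 0.27 (adjusted p = 0.433) and Dkk3 0.20 (adjusted p = 0.423). The score was above the untreated mean on 6 of 6 STZ arrays and above the highest untreated array on 4 (difference 0.146, exact permutation p = 0.004, two-sided, adjusted p = 0.016). In Ins2Akita it differed by 0.0487 (exact permutation p = 0.163, adjusted p = 0.217), and by 0.0706 without wild-type replicate 7 (exact permutation p = 0.0281, unadjusted). Camera did not call the list in Ins2Akita (adjusted p = 0.2) or in the difference between the models (adjusted p = 0.363), so a difference between them was not shown. The ciliary markers (mean log2 change 0.615) moved with this list too. With the anterior eye scores as covariates the mean of the Muller glia list was 0.149, and it was called by camera (adjusted p = 0.000979, and adjusted p = 0.0444 with an estimated correlation). The list of reactive gliosis and acute phase genes was higher (14 genes, adjusted p = 0.000449), with adjusted p = 0.0971 with an estimated correlation and 2 genes higher adjusted over the list alone. Lcn2 gave 0.51 (adjusted p = 0.252), Cp 0.39 (adjusted p = 0.337) and Serpina3n 1.42 with an SE of 0.636. Gfap gave 0.17 (SE 0.109, adjusted p = 0.704) and was detected on 0 arrays of either group. The list of complement and antigen presentation genes was higher (15 genes, adjusted p = 0.00014), with adjusted p = 0.201 with an estimated correlation and 5 genes higher adjusted over the list alone. Its leading members were the class II genes H2-Aa (0.97, SE 0.258, adjusted p = 0.184) and H2-Ab1 (0.56, SE 0.182, adjusted p = 0.284), whose probes are uncertain because these genes are polymorphic and alike. Its score differed by 0.303 (exact permutation p = 0.03, adjusted p = 0.08), and that of the microglia and macrophage list by 0.0653 (exact permutation p = 0.282, adjusted p = 0.322).

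**Figure D4:**
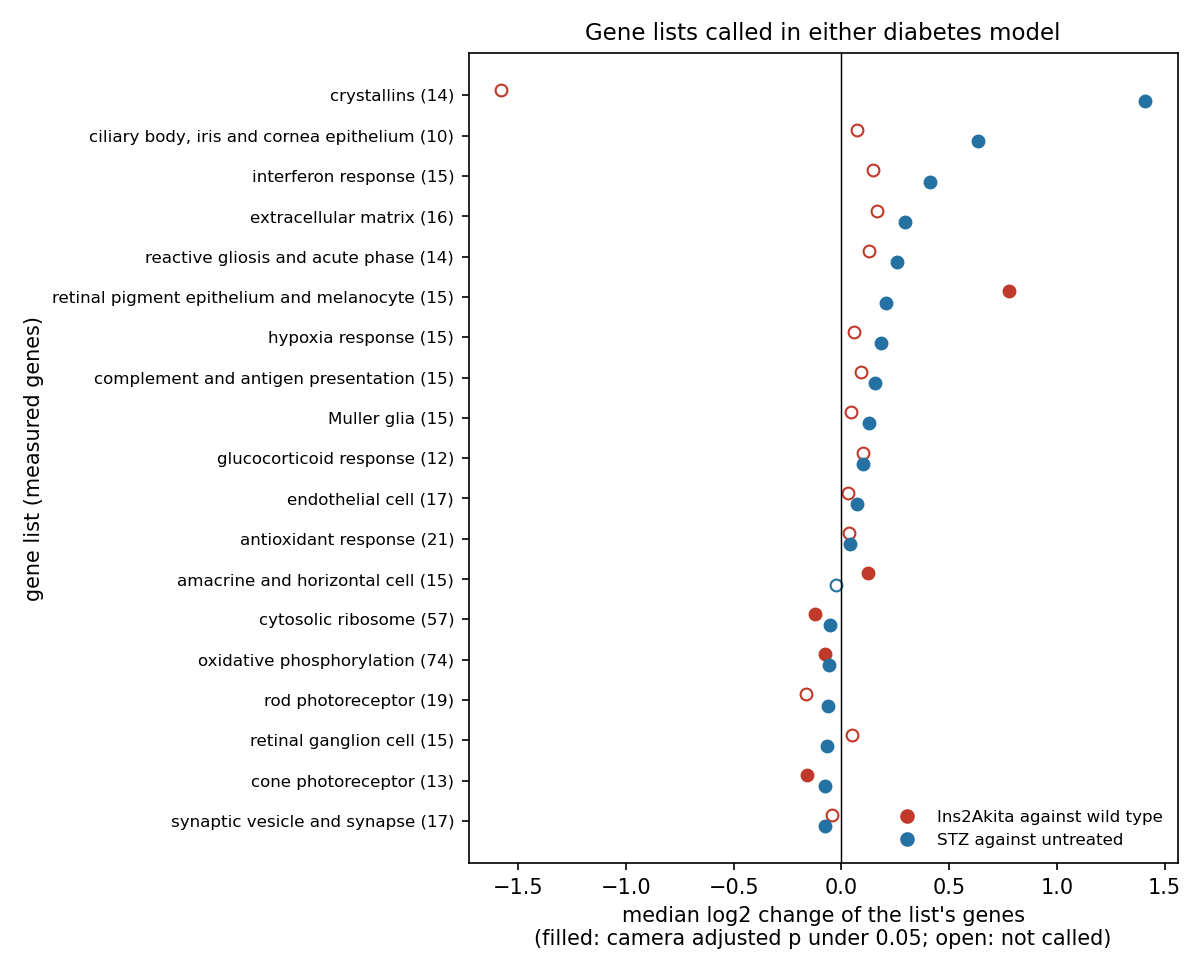
Median log2 change of the measured genes of each list (horizontal axis) in Ins2Akita against wild type (red) and STZ against untreated (blue), for the 19 lists called by camera in either. The interferon response list lay at 0.41 in STZ, crystallins were at 1.41 in STZ and -1.58 in Ins2Akita, where they were not called, and oxidative phosphorylation in Ins2Akita changed direction in the authors' series matrix values. The pigment epithelium and ciliary lists in STZ did so where their own scores were covariates, which removes their change by construction.

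Camera called 18 of 41 lists in STZ, 12 higher and 6 lower, and 16 of them were lost with an estimated correlation. In these 16 lists 0 of 343 genes passed over all genes in limma, and 39 had an unadjusted p under 0.05. Higher lists were hypoxia response (15 genes, adjusted p = 0.00373), glucocorticoid response (12 genes, adjusted p = 0.00843), endothelial cell (17 genes, adjusted p = 0.0406) and antioxidant response (21 genes, adjusted p = 0.0406). With an estimated correlation they gave adjusted p = 0.201, 0.201, 0.263 and 0.43. Adjusted over the list alone, 3 hypoxia genes and 1 antioxidant gene were higher and 0 genes of the other lists. Among their members the oxygen sensor gene Egln3 gave 0.51 (adjusted p = 0.153), the glucose transporter gene Slc2a1 0.33 (adjusted p = 0.282) and the cystine transporter gene Slc7a11 1.04 (2.05-fold, SE 0.277, adjusted p = 0.184), which passed with the anterior eye scores as covariates (1.15, adjusted p = 0.00676). Gpx3 gave 1.59 (SE 0.605, adjusted p = 0.413), Plin4 0.87 (SE 0.361, adjusted p = 0.461), Sult1a1 0.31 (adjusted p = 0.504) and Vwf 0.35 (adjusted p = 0.3). Txnip gave 0.32 (SE 0.168, adjusted p = 0.614) and Vegfa 0.10 (SE 0.0718, adjusted p = 0.779).

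Lower lists in STZ were those of neurons, protein synthesis and respiration. They were cytosolic ribosome (57 genes, adjusted p = 0.00277), cone photoreceptor (13 genes, adjusted p = 0.0155), retinal ganglion cell (15 genes, adjusted p = 0.0197), oxidative phosphorylation (74 genes, adjusted p = 0.0205), rod photoreceptor (19 genes, adjusted p = 0.0395) and synapse (17 genes, adjusted p = 0.0395). With an estimated correlation they gave, in this order, adjusted p = 0.475, 0.263, 0.201, 0.609, 0.376 and 0.263. Adjusted over the list alone, 2 cone genes were lower and 0 genes of the other 5 lists. The short-wavelength opsin gene Opn1sw gave -0.56 (SE 0.145, adjusted p = 0.177) and the cone gene Gnb3 -0.34 (adjusted p = 0.3). Uchl1 gave -0.20 (adjusted p = 0.427), the neurofilament gene Nefh -0.16 (adjusted p = 0.578) and Rps15 -0.21 (adjusted p = 0.412). Rpl27a gave -0.17 (adjusted p = 0.337), Cox7a2l -0.22 (adjusted p = 0.389), Atp5e -0.25 (adjusted p = 0.43), Pde6a -0.14 (adjusted p = 0.568) and Dlg4, the postsynaptic scaffold gene, -0.23 (adjusted p = 0.519).

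Lists of the anterior eye, crystallins, pigment epithelium and matrix were higher in STZ as well, and that of other lens fibre genes was not called (adjusted p = 0.303). Ciliary body, iris and cornea epithelium (10 genes, adjusted p = 0.000547, and adjusted p = 0.201 with an estimated correlation) had 10 of 10 genes above 0, with Wfdc2 at 0.59 (adjusted p = 0.202) and Otx1 at 1.26 (adjusted p = 0.413). Extracellular matrix (16 genes, adjusted p = 0.00103, and adjusted p = 0.201 with an estimated correlation) had Col5a1 at 0.39 (adjusted p = 0.427) and Sparc at 0.40 (adjusted p = 0.489). Crystallins (14 genes, adjusted p = 0.0195, and adjusted p = 0.609 with an estimated correlation) had a median of 1.41, with Cryba1 at 1.60 and an SE of 1.38. Pigment epithelium (15 genes, adjusted p = 0.0406, and adjusted p = 0.622 with an estimated correlation) had Trpm3 at 0.55 (adjusted p = 0.239), and its sign with the neighbouring-tissue scores as covariates is not informative, since its own score is among them (adjusted p = 0.951). Adjusted over the list alone, 1 gene was higher in the ciliary list and 1 in the pigment epithelium list, and 0 in the others. The ciliary score was 0.286 ± 0.264 in STZ (SD, n = 6) and -0.329 ± 0.558 in the untreated group (SD, n = 8). It was 0.0126 ± 0.573 in wild type (SD, n = 8) and 0.091 ± 0.429 in Ins2Akita (SD, n = 9). Between untreated and wild type 9 of the 10 ciliary genes lay below 0 (camera adjusted p = 0.571). The crystallin score was 0.869 ± 1.69 in STZ and -0.278 ± 2.23 in the untreated group. Without STZ replicate 4, the STZ array with the highest lens scores, the crystallin list was not called (adjusted p = 0.571), and 0 of its 14 genes had an unadjusted p under 0.05 on all arrays in limma. Single arrays stood apart for Sparc, Nefh and Txnip.

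**Figure D5:**
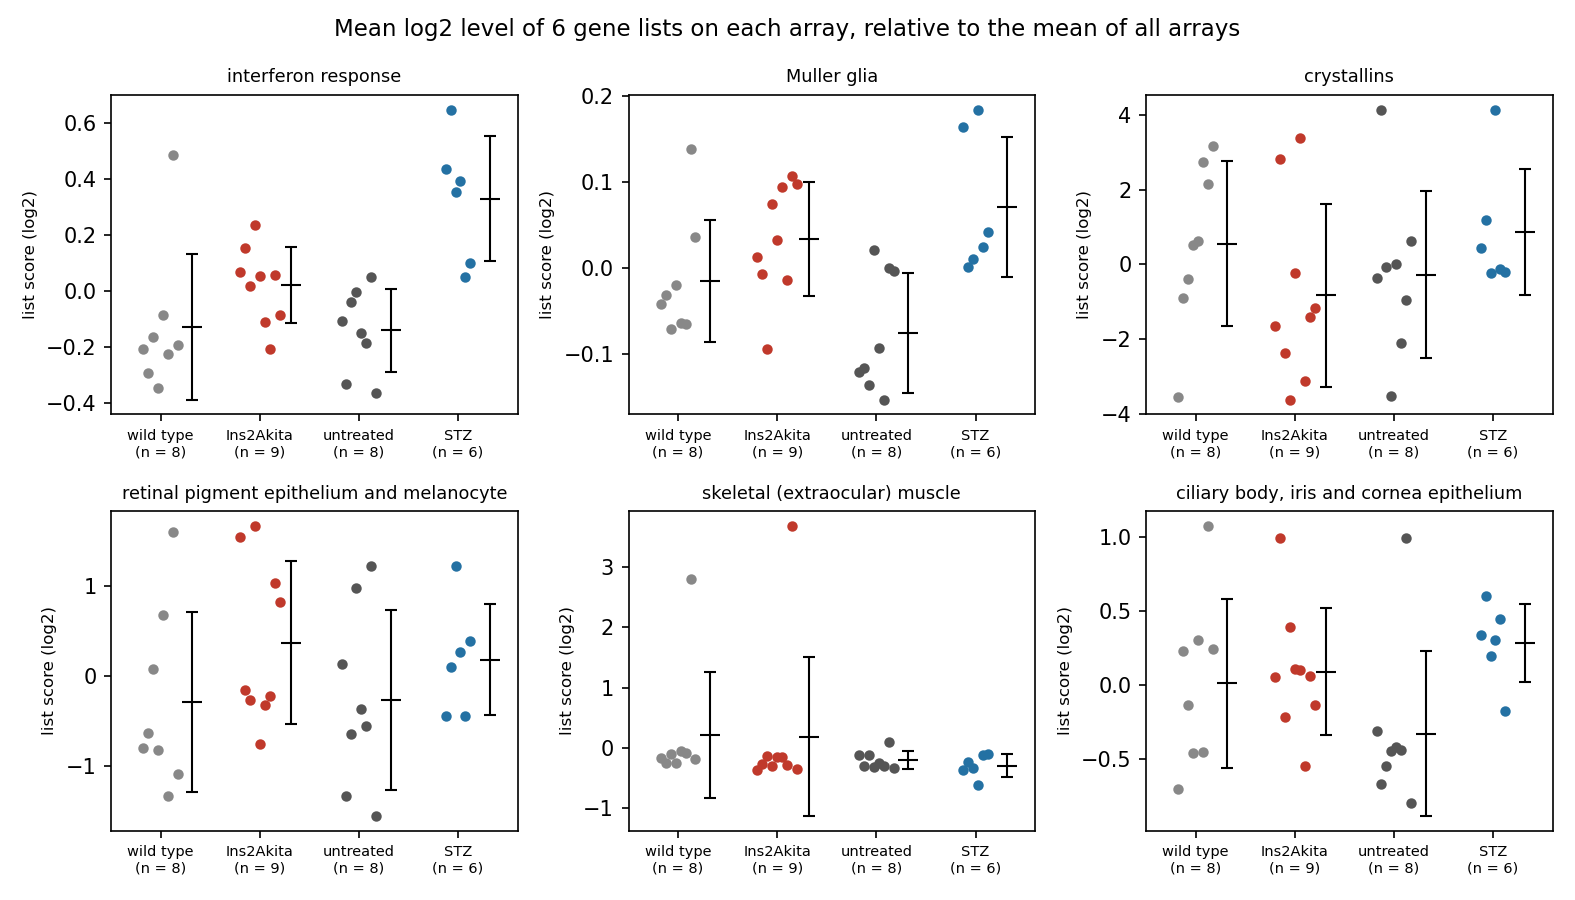
Score of 6 gene lists on each array (points), the mean log2 level of a list's genes relative to the mean of all arrays, with the group mean (bar) and SD (whisker), in the wild-type (n = 8), Ins2Akita (n = 9), untreated (n = 8) and STZ (n = 6) groups. The interferon score was 0.05 to 0.65 on the STZ arrays, and muscle markers stood apart on wild-type replicate 7 (2.8) and Ins2Akita replicate 8 (3.68).

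The count of 6 probes became 0 in limma with only these groups in the fit (1495 with an unadjusted p under 0.05) and 0 without 4 arrays that stood apart in lens or muscle markers (1127 with an unadjusted p under 0.05). It was 1 with the BeadChip as a random block, 2 in the authors' series matrix values, 2 with the neighbouring-tissue scores, 24 with array weights and 5 (4 higher and 1 lower) with the anterior eye scores. The anterior eye scores also ended the calls of the crystallin, ganglion cell and synapse lists (adjusted p = 0.374 each), the pigment epithelium and endothelial lists (0.223 each), and the antioxidant (0.0779) and rod lists (0.063). Single arrays also moved it, to 24 without wild-type replicate 7, 21 without STZ replicate 5, 3 without untreated replicates 2, 5 or 6 or STZ replicate 3, and 2 without untreated replicate 8 or STZ replicates 1 or 2. Leaving out 1 array ended the calls of the lists of pigment epithelium (9 of 31 arrays, adjusted p up to 0.284 without untreated replicate 8), antioxidant response (8, up to 0.202 without STZ replicate 4), rod (7, up to 0.119 without STZ replicate 4) and endothelial genes (7, up to 0.277 without STZ replicate 3). It also ended those of synapse (6, up to 0.13 without STZ replicate 3), oxidative phosphorylation (3, up to 0.31 without untreated replicate 1), crystallin (3), cone (0.105 without STZ replicate 3), ganglion cell (0.0643 without untreated replicate 8) and glucocorticoid response genes (0.0532 without STZ replicate 3).

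The third comparison asked where the models differed, by the change in Ins2Akita minus the change in STZ. Rpl23 (0.70, SE 0.0945, adjusted p = 0.00044) and Map1b, which encodes a microtubule-associated protein of neurons (0.68, SE 0.117, adjusted p = 0.0151), changed more upward in Ins2Akita on single probes, and the gene model Gm5347 more downward (-0.89, SE 0.16, adjusted p = 0.024). Next by p and not passing were Mef2c, a transcription factor gene (0.54, SE 0.11, adjusted p = 0.0821), and the DNA repair gene Xrcc6 (0.39, SE 0.0795, adjusted p = 0.0821). All 3 genes that passed also differed between the untreated and wild-type groups, by log2 differences of 0.65 for Rpl23, 0.37 for Map1b and -0.58 for Gm5347. The other 3 probes of Rpl23 gave -0.044, -0.088 and -0.017, and those of Map1b -0.30, 0.12 and -0.01. The Map1b probe at 0.12 was itself called lower in Ins2Akita against wild type in limma (-0.33, adjusted p = 0.0499). In STZ that probe gave -0.45 (adjusted p = 0.122). With the anterior eye scores as covariates Map1b (0.68, SE 0.133, adjusted p = 0.0569) and Gm5347 (-0.88, SE 0.184, adjusted p = 0.0885) did not pass. These were the only calls among 16743 probes in limma, and 1449 had an unadjusted p under 0.05. Of the 696 probes called in Ins2Akita, 3 passed this test.

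Besides the interferon list, camera called crystallins lower (14 genes, adjusted p = 0.000382, and adjusted p = 0.736 with an estimated correlation) and the amacrine and horizontal cell list higher (15 genes, adjusted p = 0.0217, and adjusted p = 0.519 with an estimated correlation) in this difference. Over all genes, 0 of the 44 genes of these lists passed in limma and 8 had an unadjusted p under 0.05, and 1 interferon gene was lower when adjusted over the list alone. The probe count was 12 in the authors' series matrix values (5 higher and 7 lower, against 2 and 1), 11 with array weights, 7 with a trended robust prior, 6 without the filter on dim probes and 1 with the BeadChip as a random block, with the anterior eye scores or without the 4 arrays. Without those arrays the interferon and amacrine differences were not called (adjusted p = 0.0622 for each). Median scaling gave 1 higher and 1 lower, and leaving out 1 array gave 9 (wild-type replicate 4), 5 (Ins2Akita replicate 9, STZ replicates 1 or 4) or 1 (STZ replicate 5). It also ended the call of crystallins (0.0805 without STZ replicate 4) and that of the amacrine list (up to 0.0826 without untreated replicate 3, for 5 of 31 arrays).

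The overlap of the models was 1 probe, 1 of 2 for Chrnb1, higher in both, where independent lists would share 0.106 (Fisher's exact test p = 0.101), with 0 lower in both and 0 in opposite directions. Of the 696 probes called in Ins2Akita, 501 (72.0%) had the same sign in STZ. Over all 16743 probes the changes correlated at 0.291 (Pearson) and 0.287 (Spearman), across probes that are not independent replicates. Of 100 splits of the arrays, the real one included, 9 gave a Pearson correlation as high (highest other 0.465). It fell with either set of tissue scores as covariates. At an unadjusted p under 0.05, 170 probes were higher in both (59.2 with independent lists) and 169 lower in both (78.8), while 28 and 20 went in opposite directions (63.8 and 73.2). The overlap was 0 with only the compared groups in each fit, with the BeadChip as a random block, with the neighbouring-tissue scores and without the 4 arrays, and 4 with array weights. It was 6 without wild-type replicate 7 and 2 without Ins2Akita replicates 5 or 7, untreated replicates 3 or 7 or STZ replicate 4.

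The last comparison set the non-diabetic groups against each other, as a background for the diabetes comparisons. Between untreated and wild-type mice, 3723 probes (22.2%) passed in limma, 1902 higher and 1821 lower in the untreated group, and 470 of them changed by more than 1.5-fold. The smallest p-values belonged to the interferon gamma receptor gene Ifngr2 (3.57-fold, log2 difference 1.84, SE 0.105, adjusted p = 8.92e-14, n = 8 and 8), Siglech, a lectin gene of microglia (1.52, SE 0.0927, adjusted p = 4.06e-13) and Zxda (1.32, SE 0.0826, adjusted p = 5.49e-13). The perforin gene Prf1 (1.47, SE 0.0931, adjusted p = 6.19e-13) and Mpv17l (1.28, SE 0.0816, adjusted p = 6.19e-13) came next. Ifngr2, Siglech and Mpv17l had other probes, which did not follow. Those of Ifngr2 gave -0.10 and -0.20, that of Siglech 0.03, and those of Mpv17l 0.06 and -0.12, and sequence variants under the called probes were not checked. Ifngr2 was also highest on an array, untreated replicate 7, that stood apart from its group.

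The ribosome list (57 genes, adjusted p = 9.73e-06, and adjusted p = 0.938 with an estimated correlation) and the oxidative phosphorylation list (74 genes, adjusted p = 1.55e-05, and adjusted p = 0.938 with an estimated correlation) were lower by camera in the untreated group. Of the ribosomal genes 1 rose, 18 fell and 38 did not pass, or 1 and 20 adjusted over the list alone, and of the respiratory genes 1 rose, 23 fell and 50 did not pass, or 2 and 27. Median scaling moved the split to 1166 higher and 2524 lower. Each of these groups lay on a BeadChip of its own, so that group and BeadChip cannot be told apart here, and the count with the BeadChip as a random block was 2616.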

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

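The tests of the BeadChip in the non-diabetic groups, of microglia and of an interferon effect shared with Ins2Akita were chosen after the result was seen, as were the marker scores used as covariates (lens, pigment epithelium, muscle and liver, or anterior eye), the test on sets of 4 wild-type arrays, the list scores without single arrays, and the liver and conjunctival lists.

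The first pattern was the size of the difference between the non-diabetic groups, 3723 probes between untreated and wild type. The values argue against single-probe effects as its whole cause. Other probes of the genes called had the same sign in 65.4% of 1142 cases, and 289 of them were called with that sign. Their median change was 0.306 of that of the called probe. The 95% exact binomial interval (62.6 to 68.2) treats these probes as independent, which they are not. It does not measure the spread between arrays, and agreement among genes not called was not measured. RNA of lens, pigment epithelium, muscle or liver was excluded as the whole cause of this first pattern. With these marker scores in the model the changes kept a median of 0.987 of their size (quartiles 0.947 and 1.03). RNA of ciliary body, cornea or conjunctiva was excluded likewise (1.03, quartiles 0.942 and 1.12). Hybridisation to different BeadChips stays open: Ins2Akita replicate 9, on the BeadChip of the STZ group, lay at 0.0861 between the other Ins2Akita arrays (0) and the STZ arrays (1), within the range of the former (-0.167 to 0.235), but this is 1 array. A difference between separately kept or sampled cohorts may also account for the pattern, was not tested, and cannot be told apart from one of the BeadChip for the other arrays.

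The second pattern was the 696 probes between Ins2Akita and wild type. RNA of lens, pigment epithelium, muscle or liver was excluded as its whole cause, with a median of 0.986 of the change kept (quartiles 0.924 and 1.03), and so was RNA of ciliary body, cornea or conjunctiva (0.966, quartiles 0.914 and 1.02). The BeadChip is a candidate explanation for part of it: on an axis from wild type (0) to the remaining Ins2Akita arrays (1), Ins2Akita replicate 9 lay at 0.497, below the other 8 (0.67 to 1.02), although this too is 1 array. An effect of diabetes that STZ shares was left undecided, since 9 of 100 splits of the untreated and STZ arrays, the real one included, gave changes that correlated as highly with those of Ins2Akita (0.291, highest other 0.375). A wild-type group that differed from the other groups was left undecided too, since with separate sets of 4 wild-type arrays a median of 68.6% of probes (53.6 to 79.3 over 70 splits) had the same sign between untreated and wild type, and an effect of the Ins2 mutation itself was not tested.

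The third pattern was the higher interferon response in STZ, which was called under each of 43 alternatives (adjusted p 1.04e-16 to 0.0297). The values argue against more microglia as its whole cause. The microglia and macrophage list had a mean log2 change of 0.0653 (SE 0.0409, 14 genes) against 0.472 (SE 0.075, 15 genes) for the interferon list. These SEs are over genes, which are not independent, and do not measure the spread between arrays. With each STZ or untreated array left out in turn, the microglia score differed by 0.0258 (without STZ replicate 1) to 0.0918 (without STZ replicate 6). The interferon score differed by 0.408 (without STZ replicate 2) to 0.528 (without STZ replicate 5). RNA of lens, pigment epithelium, muscle or liver was excluded as its whole cause, with a median of 0.837 of the change kept (quartiles 0.706 and 0.997). RNA of ciliary body, cornea or conjunctiva stays open as a cause for part of it (0.839, quartiles 0.191 and 0.889, mean change 0.347 against 0.472). The interferon list was called by camera with those scores too (adjusted p = 1.98e-08). A response to diabetes that Ins2Akita shares stays open, because the difference between the models gave an adjusted p of 0.519 with an estimated correlation and the score difference in Ins2Akita was 0.237 (0.149 on all arrays) without wild-type replicate 7. Entry of other leukocytes, an effect of STZ as a compound, of injection or of housing may also account for it and were not tested, and the BeadChip cannot be told apart from the treatment here.

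Of 100 splits of the same arrays, the real one included, 1 gave as many probes as Ins2Akita against wild type (696, highest other 162) and 1 as many as the difference between the models (3, highest other 1). For untreated against wild type the number was also 1 (3723, highest other 910). Chance alone is thus unlikely for these 3 counts, 1 of 100 being the smallest share that these splits can give. No correction was made for the number of counts tested. The count of 3 for the difference became 1 without STZ replicate 5. For STZ against untreated it was 3 (6, highest other 46), a share that makes chance less likely without excluding it, since 2 other splits gave as many. The split of the untreated and STZ arrays with 46 probes set untreated replicates 1, 3, 4 and 5 with STZ replicates 1 and 2 against the rest, and may point to a structure of these samples, which was not tested further. Among the lists, 1 of 100 splits gave as many as STZ (18, highest other 15), so chance alone is unlikely there. Of these 18 lists, 16 were lost with an estimated correlation. Chance stays open for the lists called in Ins2Akita (5, highest other 19, in 49 of 100 splits as many), in the difference between the models (3, highest other 18, 79 of 100) and between untreated and wild type (2, highest other 17, 89 of 100).

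A test of the difference itself separated the models for single probes of Rpl23 (0.70), Map1b (0.68) and Gm5347 (-0.89), log2 changes in Ins2Akita minus those in STZ, while the other probes gave -0.044, -0.088 and -0.017 for Rpl23 and -0.30, 0.12 and -0.01 for Map1b. By camera the interferon response list (adjusted p = 0.000138), crystallins (0.000382) and the amacrine and horizontal cell list (0.0217) also differed, and with an estimated correlation none of the 3 did (adjusted p = 0.519, 0.736 and 0.519).

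Single arrays stood far from the others of their group in 17 of 242 groups of values of the genes tested, a set narrowed to those named here after a wider set had been seen, 9 of 44 of list scores and 0 of 4 of detected probes, and chance alone gives about 1 in 20. Among wild-type arrays these were, in log2 intensity and with the nearest other array, Rpl19 on replicate 6 (10.8, nearest 10.38), Pde6b on replicate 8 (13.85, lowest, nearest 14.24), Abca4 on replicate 5 (12.33, nearest 11.88), Opn1sw on replicate 5 (8.39, nearest 7.96), Tkt on replicate 7 (11.31, nearest 10.88) and Cspg4 on replicate 1 (6.01, nearest 5.72). The interferon genes Ifi27l2a and Ifitm3 were highest on wild-type replicate 7 (6.99, nearest 5.87, and 9.93, nearest 8.85), where the interferon score was 0.485 (nearest -0.085). Among Ins2Akita arrays they were Ch25h on replicate 2 (4.49, lowest, nearest 5.64) and Uchl1 on replicate 9 (9.35, lowest, nearest 9.54). Among untreated arrays they were Nefh on replicate 8 (9.57, nearest 9.33), Ifngr2 on replicate 7 (12.3, nearest 12.12) and Rin3 on replicate 1 (6.94, nearest 6.78). Among STZ arrays they were Sparc on replicate 4 (10.67, nearest 9.93), Txnip on replicate 3 (7.61, nearest 7.07), Mef2c on replicate 1 (11.41, nearest 10.98) and Ckmt2 on replicate 5 (7.54, nearest 7.09).

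Scores of tissues outside the retina stood apart on several arrays. The crystallin score was 4.13 on STZ replicate 4 (nearest 1.19), and that of other lens fibre genes 4.29 on the same array (nearest 0.327) and 4.69 on untreated replicate 2 (nearest 0.144). The ciliary, iris and cornea score was 0.997 on untreated replicate 7 (nearest -0.309). Skeletal muscle genes stood at 2.8 on wild-type replicate 7 (nearest -0.0461) and 3.68 on Ins2Akita replicate 8 (nearest -0.128). Liver and plasma genes stood at 3.57 on Ins2Akita replicate 1 (nearest 0.866), and conjunctival genes at 1.51 on Ins2Akita replicate 2 (nearest 0.205).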

How the results depend on the processing

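The neighbouring-tissue scores and the anterior eye scores as covariates and the leaving out of 4 arrays were chosen after the result was seen, and the other alternatives before. Values are counts of probes called unless a list, gene or correlation is named, and the cause of a change was not tested unless given. The covariates are the neighbouring-tissue scores unless the anterior ones are named. Untreated against wild type gave 2616 to 3889 in every alternative, against 3723.

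Ins2Akita against wild type went from 696 to 3953 in the authors' series matrix values. There the median log2 change of all probes was -0.086, against -0.000922 in the fit as planned. These calls therefore include a shift of all probes to lower values. The count was 448 with only the groups compared (fewer samples), 446 with the covariates and 228 with the BeadChip as a random block. With that block all 155 genes called were among the 488 called before. STZ against untreated went from 6 to 2 in the series matrix, 24 with array weights, 0 with only the groups compared, 1 with the BeadChip block, 2 with the covariates and 0 without the 4 arrays. For these counts of 0 in limma, 1495 and 1127 probes had an unadjusted p under 0.05. The difference between the models went from 3 to 12 in the series matrix, 6 without a filter, 7 with a trended robust prior, 11 with array weights, 1 with the BeadChip block, 5 without Ins2Akita replicate 9, 1 with the anterior scores and 1 without the 4 arrays. The mean effect went from 502 to 291 with median scaling, 2878 in the series matrix (13.5% higher against 48.0%), 125 with the BeadChip block, 117 with the covariates, 322 with the anterior scores and 277 without the 4 arrays. The overlap of 1 probe became 4 with array weights and 0 with only the groups compared, with the BeadChip block, with the covariates and without the 4 arrays. The correlation of the changes fell from 0.291 to 0.183 with the covariates and 0.166 with the anterior scores.

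Of the lists called, 0 of 5 in Ins2Akita, 2 of 18 in STZ, 0 of 3 in the difference and 0 of 2 between the non-diabetic groups remained with an estimated correlation. The rotation test fry called 4, 3, 0 and 4 lists. Those in the difference were 8 in the series matrix, 5 with the covariates and 1 without the 4 arrays, and those in STZ 10 with the anterior scores. Directions reversed for oxidative phosphorylation in Ins2Akita (adjusted p = 0.788) and for Tubb3 (-0.040) and Gfap (-0.14) in the series matrix, and with the covariates for Txnip in Ins2Akita (-0.018) and the pigment epithelium list in STZ (adjusted p = 0.951). The ciliary list in STZ reversed with the anterior scores (adjusted p = 0.941). Both lists were adjusted for their own score, which removes their change by construction. In the fit as planned Tubb3, Gfap and Txnip gave 0.27, 0.12 and 0.17, and none of the 3 was called.

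With the replicate number as a block the counts were 848 for Ins2Akita, 17 for STZ, 3 for the difference, 623 for the mean and 3889 between the non-diabetic groups, with an overlap of 4. Same-numbered arrays correlated over 0.1 in 3 of 8 pairs of wild type and Ins2Akita and in 1 of 6 of untreated and STZ. In each set 1 array correlated best with its own number. These correlations did not show that the numbers pair the samples, and so few pairs cannot exclude it. The replicate numbers follow the position of each array on its BeadChip, apart from the Ins2Akita array on the BeadChip of the STZ group. This block therefore also takes up differences between array positions, which were not tested apart from it. Of 174 gene results the block ended 3 calls and made 1, and of 28 list results it ended 0.

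Leaving out each array in turn gave 470 (wild-type replicate 6) to 781 for Ins2Akita, 2 to 24 (wild-type replicate 7) for STZ, 1 (STZ replicate 5) to 9 (wild-type replicate 4) for the difference and 303 (STZ replicate 1) to 711 for the mean, which was 334 without STZ replicate 4. It gave 3069 to 3844 between the non-diabetic groups, 1 to 6 for the overlap (wild-type replicate 7) and 0.2 to 0.358 for the correlation. Lists called were 3 (wild-type replicate 6 or Ins2Akita replicate 4) to 8 (Ins2Akita replicate 6), 10 (STZ replicate 3) to 19, 1 (STZ replicate 4) to 7 (STZ replicate 6) and 2 to 2.

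Of 174 gene results 172 kept their direction and side of the threshold with no background step, 164 with median scaling, 152 in the series matrix, 139 with the BeadChip block, 154 with the covariates, 159 with the anterior scores and 158 without the 4 arrays. Of 28 list results the numbers were 28, 27, 21, 26, 19, 18 and 24. The interferon and Muller glia lists in STZ were called in all 43 of their alternatives, single arrays left out included (adjusted p 1.04e-16 to 0.0297 and 5.2e-05 to 0.0297). Signal over background limits dim genes, such as Gfap and Ins2, most.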

Other observations

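The marker lists of liver and conjunctiva and the genes named in this part were chosen after their values were seen, while the mean effect over both models was planned. The mean of the changes in Ins2Akita and STZ passed in limma for 502 probes, and for 364 genes on their brightest probe. Of these probes 241 were higher and 261 lower, with a median of 1.19-fold and 9 over 1.5-fold. An unadjusted p under 0.05 was found for 3176 probes. The count was 2878 in the authors' series matrix values (389 higher and 2489 lower), 125 with the BeadChip as a random block and 117 with the neighbouring-tissue scores. Leaving out each array in turn gave 303 to 711. Interferon-inducible Ifi27l2a was higher by a mean log2 change of 1.12 (SE 0.268, adjusted p = 0.0203, 0.94 in Ins2Akita and 1.29 in STZ) and Ifitm3 by 0.73 (SE 0.182, adjusted p = 0.0252, 0.57 and 0.89). Ch25h was higher by 1.06 (SE 0.209, adjusted p = 0.00712, 1.01 and 1.10), the cystine transporter gene Slc7a11 by 0.70 (SE 0.186, adjusted p = 0.034, 0.37 and 1.04) and Adamts19 by 0.66 (SE 0.127, adjusted p = 0.00603, 0.70 and 0.63). The short-wavelength opsin gene Opn1sw was lower in the mean (-0.44, SE 0.0976, adjusted p = 0.0132, -0.32 and -0.56). The muscle LIM protein gene Csrp3 (-0.46, adjusted p = 0.00728, -0.46 and -0.46) and the mitochondrial creatine kinase gene Ckmt2 (-0.40, adjusted p = 0.00575, -0.43 and -0.37) were lower as well, although the other probe of Ckmt2 gave -0.08 in each model. So were Rin3 (-0.40, adjusted p = 0.000619, -0.53 and -0.26) and the leukotriene pathway gene Alox5ap (-0.41, adjusted p = 0.0267, -0.43 and -0.40). None of the genes named here passed in STZ alone in limma (adjusted p = 0.177 to 0.427), so a mean that passes does not show a change in each model.

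Other probes of the genes called in the mean had the same sign in 78.4% of 134 cases (95% exact binomial interval 70.4 to 85). For Ins2Akita alone the share was 60.4% of 212 (53.5 to 67). These intervals treat probes as independent, which they are not, and do not measure the spread between arrays. The median change of the other probes was 0.394 of that of the called probe for the mean and 0.155 for Ins2Akita. In Ins2Akita 8 of the 212 were called with the same sign. Of 100 splits, the real one included, 1 gave as many probes for the mean (502, highest other 1), so chance alone is unlikely. For the overlap of the models 1 of 100 splits gave as many (1 probe, highest other 0), but the other splits called so few probes that they could hardly overlap. Fisher's exact test gave p = 0.101, so chance is left open there. It could not be excluded for the correlation of their changes, for which 9 of 100 splits gave as much (0.291, highest other 0.465).

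Marker genes of tissues that are not retina stood high on some arrays, and those of lens were high on many. On Ins2Akita replicate 1 the liver genes Apoa2, Serpina1b and Cyp2e1 reached log2 intensities of 12.04, 11.3 and 10.54, against medians over all arrays of 7.35, 6.02 and 5.49. The liver and plasma score was -0.628 ± 0.721 in wild type (SD, n = 8), 0.105 ± 1.53 in Ins2Akita (SD, n = 9), 0.0992 ± 1.48 in the untreated group (SD, n = 8) and 0.548 ± 1.35 in STZ (SD, n = 6). Its highest values in these groups were, in this order, 0.852, 3.57, 3.06 and 2.8. Lens genes reached 14.5 for Crybb2 on untreated replicate 2 and 13.52 for Mip on STZ replicate 4. Their medians over all arrays were 11.42 and 7.06 and their lowest values 4.83 and 4.48. The myosin light chain gene Myl1 reached 10.76 on Ins2Akita replicate 8 against a median of 4.98, and the conjunctival gene Stfa1 11.23 on Ins2Akita replicate 2 against 8.10. The haemoglobin gene Hba-a1 ran from 10.11 to 13.56, highest on untreated replicate 1. Camera called neither the list of other lens fibre genes (adjusted p = 0.527 in Ins2Akita and 0.303 in STZ) nor that of skeletal muscle (0.978 and 0.771).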
